A study of Mus musculus with 12 samples.

How the data were processed

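The samples were total RNA from the fracture callus of mice with a fixed closed fracture of the femur, taken 7, 10 and 14 days after fracture from WT mice and from mice labelled HET for HIF-1a. Per the labels' protocols, each pool combined the RNA of 3 animals in equal parts, and 3 ug of it was amplified and labelled with biotin by the AmpoLabeling-LPR method. Each labelled pool was measured on a focused membrane array. The series holds 2 array types, one for hypoxia genes and one for angiogenesis genes, and each of the 6 combinations of genotype and day has 1 array of each type, 12 arrays in all. The labels do not say whether both array types were hybridised with RNA of the same pool. With 1 array per group there is no spread between animals or between repeat arrays at any day.

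Each scanner file holds the density of 112 spots on a linear intensity scale, with no local background column, per the file headers. The software and settings that turned the image into densities are not given in the sources used here. Each array type has 106 gene spots of 100 genes and 6 control spots, which hold PUC18 plasmid DNA or nothing. The series matrix that the authors deposited holds a ratio per spot. Set against the scanner files, every filled value equalled the spot's density minus the lowest density of its array, divided by the mean density of the Actb spots minus that lowest density, on all 12 arrays. It is therefore on a linear scale with Actb at 1, it is not centred, and its direction is that of the densities. Between 24 and 64 of the 112 spots are filled per array, and the medians of the filled ratios per column ran from 0.0017 to 0.75. The rule by which dim spots were emptied is not given in the sources used here, and 7 spots brighter than the dimmest filled spot of their array are empty as well. Actb stood at the scanner's ceiling on 11 of the 12 arrays, all but the hypoxia array labelled WT at day 7. Of the 188 gene symbols on the 2 array types, 167 are current in the RefSeq annotation of GRCm38.p6, 21 are older names with 1 current gene, and 0 stayed unmatched. Symbols are given as on the array, and no coordinates are given because the arrays name no probe positions.

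The series holds 13 scanner files for its 12 samples, since the angiogenesis sample labelled HET at day 7 has 2. One of them is headed as the WT day 7 array and is identical to that array's file in 112 of 112 spots, and the other gives the sample's values in the series matrix. Only the latter was used.

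Intensities were corrected with limma's normexp method on all spots (limma 3.58.1, R 4.3.3). The offset was 25.9, which is 10% of the median gene spot density over the 12 arrays (259.0), as set for arrays with a median under 500. Values were then taken to log2, averaged over the spots of a gene, and quantile normalized between the 6 arrays of one type, with control spots left out. A gene was above background on an array if any of its spots was brighter than the brightest control spot of that array. A gene above background on 1 array of a pair has only a bound on its difference, computed against the dimmest gene above background on the other array or the gene's own value there, whichever was higher. Bounds hold on the normalized scale, and quantile normalization can make them larger than the difference of the densities themselves, or give a bound where the densities give none. Between groups of arrays, a gene above background on no array of one group has a bound computed in the same way from group means of normalized log2 values, and no fold where that bound runs against the brighter group. A gene above background on neither array has no fold. The highest density of each array lay between 47484 and 50779, and many genes stood just below it, so a gene was taken to be at the ceiling at 90% or more of the highest density on any array (45701), and a gene at the ceiling on both arrays of a pair has no fold. The precision of an array is limited by its number, by this ceiling and by the control spots. The only repeated measure within an array is the spots of the 4 reference genes, whose pooled standard deviation over 29 sets of spots above background and below the ceiling was 0.52 log2 units, with a median of 0.11 and a largest value of 1.96, for Rpl13a on the hypoxia array labelled HET at day 7.

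At each day the difference HET minus WT is given on the log2 scale without a test, with the number of genes that differ by at least 1 log2 unit (2-fold). The genotype effect over the 3 days was fitted with limma (lmFit and eBayes) with day as a block, which leaves 2 residual degrees of freedom per gene, and the day 14 minus day 7 difference was taken from the same fit. The 3 days are different time points and not repeat samples of a group, so the residual is the variation of the genotype difference between days plus array error. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes above background on at least 1 of the 6 arrays and a threshold of 0.05. Gene lists, 20 in all, were tested with limma's fry where at least 3 members were above background, in its directional form and in its mixed form, and lists with fewer were only counted. Members were matched by the symbols on the arrays. This left out Cxcl4 (now Pf4) of the angiogenesis inhibitors and Idb3 (now Id3) of the transcription and cell signalling genes, which the lists hold under their current names. The list medians at each day were set among 10000 random lists of the same size matched on mean level, drawn from the genes with a fold at that day. The fits were tested on 100 simulated data sets per array type with 10 changed genes each. Normal noise with the standard deviations of the fit was added to the genes' mean normalized values. No background limit, ceiling or renewed normalization was simulated, so the shares do not cover genes near those limits. For the genotype effect on the hypoxia array (73 genes), 49.9% of changes of 2 log2 units, 93.6% of 4 and 98.7% of 6 were recovered. On the angiogenesis array (96 genes) the shares were 35.1%, 96.5% and 99.6%. Between 0.34 and 0.82 unchanged genes per data set were called in these genotype tests. For day 14 against day 7 the shares were 14.3%, 85.6% and 96.8% on the hypoxia array. They were 14%, 93.3% and 99.7% on the angiogenesis array.

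The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, per array type, Hif1a, the 5 genes with the largest difference in each direction at each day, the 10 largest among genes that differ in one direction at all 3 days, at most 10 genes per direction past the threshold in a fit, and at most 4 members of each list by mean difference. Some genes that the rule names are not reported here, although the counts include them. The ceiling, the use of bounded differences in ranking, the restriction of list medians to genes with a fold, the use of 1 background threshold for all arrays of a type (the brightest control spot of any array, or the lowest of the arrays' own thresholds) and an alternative without normalization and without day 7 were chosen after seeing the data. Alternatives were scaling each array to its median or to its reference genes, no normalization between arrays, the series matrix, no background correction, an offset 5 times higher, no filter on dim genes, only genes above background on all arrays compared, fits without each day, without the day block or the genotype term, and limma's trend option. Figures were drawn with matplotlib 3.10.9.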

Results

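The study asked how gene expression in the healing callus of a broken femur differs between WT mice and mice labelled HET, which per the series title are partly deficient in HIF-1alpha, at 7, 10 and 14 days after fracture. Pooled callus RNA of 3 animals per group was hybridised to focused membranes for hypoxia genes and for angiogenesis genes, 1 array per genotype, day and array type, so no value below has a replicate. Median spot densities ranged from 4.83 on the hypoxia WT array at day 7 to 1415 on the angiogenesis WT array at day 10. On the hypoxia arrays, 27, 56 and 42 of 100 genes were above background in WT at days 7, 10 and 14, and 20, 53 and 46 on the arrays labelled HET. The angiogenesis arrays held 9, 76 and 79 such genes in WT and 12, 91 and 44 on the arrays labelled HET. The order of the genotypes depended on the threshold on the hypoxia arrays at days 7 and 10 and on the angiogenesis arrays at day 10. With 1 threshold for all arrays of a type, the brightest control spot of any of them, the counts on the hypoxia arrays were 14 in WT and 17 in HET at day 7, and 34 and 53 at day 10. On the angiogenesis arrays at day 10 they were 76 and 55. At day 14 the hypoxia arrays held 19 in WT and 20 in HET, the same order as with their own thresholds. With the lowest of the arrays' own thresholds, they held 82 genes in WT and 63 in HET. However, 6 control spots of the WT array and 4 of the HET array lay above that threshold too, so these counts do not decide the order. Quantile normalization was applied across arrays that differ this much in detected genes. The direction of many differences depended on the scaling. Of the genes that the rule for named genes selects, 7 of 16 with a difference other than 0 at day 7, 13 of 25 at day 10 and 8 of 31 at day 14 changed direction on the hypoxia arrays under at least 1 of 3 other scalings (median, reference genes, none). The angiogenesis arrays had 0 of 4, 20 of 45 and 20 of 31 such genes.

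**Figure D1:**
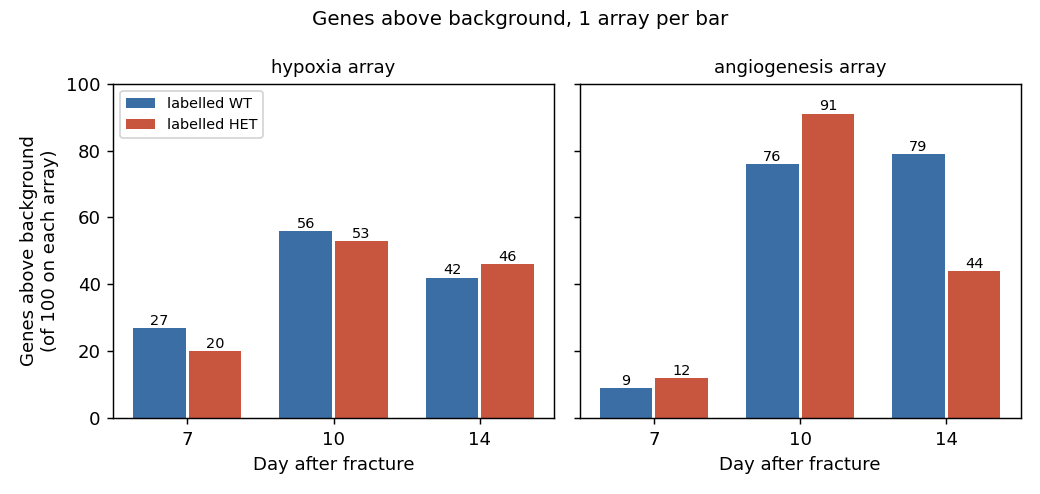
Bars give the number of genes above background (y axis, of 100 genes on each array) by day after fracture (x axis) for the arrays labelled WT and HET, 1 array per bar, for both array types. Day 7 has the fewest genes in every series of bars, with 9 and 12 on the angiogenesis arrays, and the widest gap between genotypes is 79 against 44 on the angiogenesis arrays at day 14.

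Hif1a, the gene for the oxygen-regulated subunit of the HIF-1 transcription factor and the gene targeted in these mice, was brighter on both day 7 arrays labelled HET than on their WT partners and dimmer on the 4 later ones. On the hypoxia arrays its density in WT was 137 at day 7, 30822 at day 10 and 15394 at day 14, against 5509, 18939 and 4766 on the arrays labelled HET. The angiogenesis WT arrays stood at 8037, 11449 and 11008, and the arrays labelled HET at 25140, 6924 and 6574. After normalization the HET minus WT difference was 0.71, -2.22 and -1.06 log2 units on the hypoxia arrays and 0.35, -0.19 and 0.00 on the angiogenesis arrays at days 7, 10 and 14. Without normalization the differences were 5.01, -0.70 and -1.69 on the hypoxia arrays and 1.64, -0.73 and -0.73 on the angiogenesis arrays. When each array was scaled to its median, the angiogenesis values turned to 0.88 at day 10 and 2.15 at day 14. The day 7 signal goes against the label, so day 7 results are given for the array labelled HET. Where the Hif1a probe lies relative to the altered part of the gene is not given in the sources used here, so the signal is not a check of the labels.

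**Figure D2:**
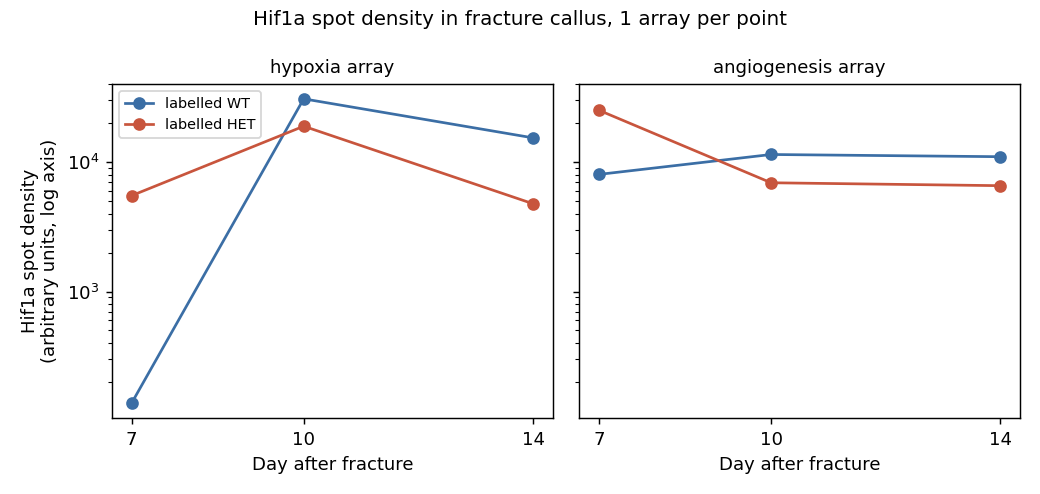
Points give the mean Hif1a spot density in arbitrary units (y axis, log scale) by day after fracture (x axis) on the arrays labelled WT and HET, 1 array per point, for both array types. The array labelled HET is the brighter of the pair at day 7 and the dimmer at days 10 and 14 on both array types, for example 5509 against 137 at day 7 on the hypoxia arrays.

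On the hypoxia arrays at day 7, the acute-phase cytokine gene Il6 had the largest difference, 2.91 log2 units higher on the array labelled HET, with a density of 12510 against 28.6. Ptx3, a secreted pattern-recognition protein gene, was above background only on the array labelled HET and at least 1.93 log2 units higher. The ribosomal protein gene Rpl13a was 1.23 higher, from a WT density of 12.7 that equals the brightest control spot and from HET spots that differ with a standard deviation of 1.96 log2 units. The phosphatase subunit gene Ppp2cb was 0.95 higher and Gapdh 0.74 higher, although Gapdh turned to -0.14 when arrays were scaled to their reference genes. The fatty acid binding protein gene Fabp4 differed by -1.87 and the endothelin-converting enzyme gene Ece1 by -0.74, the secretory granule gene Chga by -1.66 and Rps7 by -0.45. Th, above background only in WT, had a bound of -0.69 after normalization and none without it. Fabp4 was at -0.09 without normalization. The directions of Ece1 and Chga were not stable, since their unnormalized differences were 1.64 and 0.42. In all, 3 genes were at least 2-fold higher and 2 at least 2-fold lower among the 20 genes with a fold, and 7 and 1 without normalization or with median scaling. Col1a1, the main collagen gene of bone, differed by -0.02 near the ceiling and by 0.14 without normalization. No member of the glycolysis list had a fold at this day.

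At day 10 the hypoxia arrays showed 6 genes at least 2-fold higher in HET and 7 at least 2-fold lower among 48 with a fold. The RNA-binding protein gene Khsrp was 1.84 log2 units higher, the cytokine genes Il6 and Il1b 1.76 higher each, Rpl13a 1.28, and Rps2 and the survival gene Bcl2 1.11 higher each. Khsrp, Rpl13a and Bcl2 kept their direction when arrays were scaled to their median or reference genes or left unnormalized, while Il6, Il1b and Rps2 turned to -0.52, -0.78 and -1.61 under median scaling. Below Hif1a at -2.22, the lowest differences were -1.64 for the catalase gene Cat, -1.51 or lower for the transcriptional repressor gene Dr1, -1.11 for Ppp2cb, and -1.03 for the spectrin gene Spnb2. Without normalization Spnb2 was at 0.08 and Ppp2cb at -0.06. Bax, which promotes apoptosis, was above background only in WT and had a bound of -0.74 after normalization and none without it. The hexokinase gene Hk2, of the glycolysis list, was above background only in WT and had a bound of -0.41 after normalization, but its density was the higher one in HET, with an unnormalized difference of 0.72. Vegfa, a main endothelial growth factor gene, was at least 0.36 higher, with a bound of 2.77 without normalization. The angiogenesis arrays of the same day did not repeat this, with Vegfa at 0.00 after normalization and at -1.45 without it. In the list of transcription and cell signalling genes, 4 members had a fold, and Camk2g, Fos, Notch1 and Agtpbp1 differed by -0.92, -0.53, 0.49 and 0.07. Fos turned to 0.85 without normalization and Agtpbp1 to -0.49 under median scaling. The split of 6 higher and 7 lower genes became 24 and 3 without normalization, 21 and 7 with reference gene scaling and 2 and 21 with median scaling.

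At day 14, 7 genes were at least 2-fold higher and 8 at least 2-fold lower in HET on the hypoxia arrays among 46 with a fold. The hypoxia-responsive repressor gene Bhlhb2 (now Bhlhe40) was 3.14 log2 units higher, with a density of 2042 against 341. At day 10 it had differed in the other direction, by -1.02 (density 3333 against 8227), and it was below 0 there under the other scalings too. The proteasome subunit gene Psmb3 was 2.17 higher, the glycolytic enzyme gene Eno1 1.86 higher, the erythropoietin gene Epo 1.62 higher and the protease inhibitor gene Cstb at least 1.44 higher. These 5 genes also lay above 0 at day 14 under each of the other scalings, but without normalization they were at 2.50, 0.50, 1.22, 0.86 and, for the bound of Cstb, 0.58, whereas Tgfb1, at 1.14, was at -0.04 without normalization. Eno1 and Epo stood at the background limit in WT, with densities of 135 and 130 against 128.5 for the brightest control spot. In HET they stood at 348 and 254. The mitochondrial carrier gene Ucp2 differed by -2.91, with densities of 998 against 6366. Rps2 differed by -2.22, Il6 by -2.05, Ppp2cb by -1.93, Spnb2 by -1.16, the kinase gene Dapk3 by -1.34 or lower and the glycolytic enzyme gene Gpi1 by -1.20 or lower. All 8 lower genes stayed below 0 under the other scalings. Of the glycolysis list, Eno1 and Gpi1 thus lay on opposite sides of 0. The growth factor gene Igf2 differed by -0.67, and the matrix protease gene Mmp14 by -0.75 or lower. Without normalization 2 genes were higher and 18 lower, with reference gene scaling 5 and 17, and with median scaling 13 and 5.

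**Figure D3:**
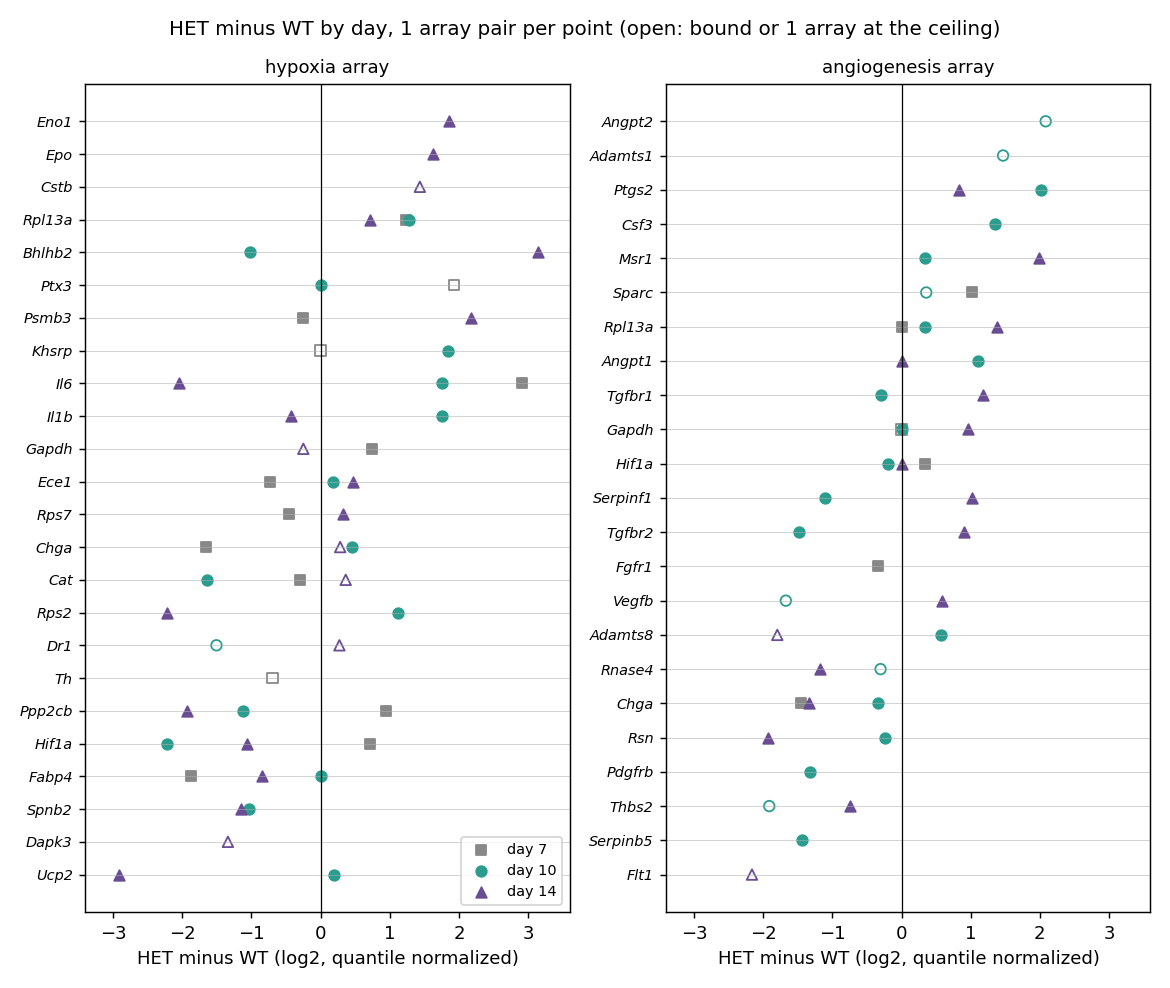
Points give the HET minus WT difference of normalized log2 values (x axis) at days 7, 10 and 14 for Hif1a and the genes with the largest differences at any day (y axis), 1 array pair per point, with open symbols for bounds and for pairs with 1 array at the ceiling. Il6 lies at 2.91 at day 7, 1.76 at day 10 and -2.05 at day 14, and 2 of the named genes, Rpl13a on the hypoxia array and Chga on the angiogenesis array, lie on one side of 0 at all 3 days, a direction that fails for both under another scaling.

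On the angiogenesis arrays at day 7 only 7 genes had a fold. Sparc, a matrix glycoprotein gene of bone, was 1.02 log2 units higher on the array labelled HET (density 5865 against 402), and Chga was at -1.46 (590 against 2194). Both kept their direction under the other scalings. The receptor gene Fgfr1 differed by -0.35. The endothelial marker, angiopoietin, ephrin, VEGF and TGF-beta lists had no member with a fold, since their genes were below background on both arrays.

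At day 10 the angiogenesis arrays showed 6 genes at least 2-fold higher and 10 at least 2-fold lower in HET among 77 with a fold. Of the 4 genes of the angiopoietin and Tie list, which act on vessel stability, Angpt2 was at least 2.08 log2 units higher and Angpt1 1.11 higher, while the receptor gene Tek was at -0.50 and Tie1 had only a bound, at 0.00 after normalization and none without it. The list median of 0.56 lay at percentile 97.8 of random lists. The prostaglandin synthase gene Ptgs2 was 2.01 higher, the protease gene Adamts1 at least 1.47, the granulocyte colony-stimulating factor gene Csf3 1.35 and the scavenger receptor gene Cd36 1.07. All 6 higher genes kept their direction under the other scalings, although the values without normalization were smaller, at 1.28 for Ptgs2, 0.77 for Angpt1, 0.43 for Cd36 and 0.22 for Csf3, with bounds of 1.31 for Angpt2 and 0.30 for Adamts1. Among angiogenesis inhibitors, 4 of 8 genes with a fold were at least 2-fold lower and 0 higher, with a list median of -0.68 at percentile 1.6. They included Thbs2 at -1.91, Timp2 at -1.22, Serpinf1 at -1.11 and Timp1 at -1.03. These values leave out Cxcl4 (now Pf4), which the list holds under its current name. It differed by -1.08, and by -0.86 under median scaling. Under median scaling none of the 4 counted genes was at least 2-fold lower, with Timp2 at -0.32, Serpinf1 at -0.75 and Timp1 at -0.97. Thbs2, which was at the ceiling in WT and enters the count and the median at its measured value, turned to 1.26 there and was at -0.35 without normalization. The endothelial growth factor gene Vegfb differed by -1.67 or lower, the receptor genes Tgfbr2 and Pdgfrb by -1.49 and -1.32, the serpin gene Serpinb5 by -1.44 and the integrin gene Itga5 by -1.05. In the list of proteases and their inhibitors 1 gene was at least 2-fold higher and 2 lower of 8 with a fold, and the median was -0.63 at percentile 1.4, with Plau at -0.62. Timp1 and Timp2 belong to both lists. The 9 chemokine and cytokine genes with a fold had a median of 0.27 at percentile 91.2, with Ifna1 at 0.60 and Ccl2 at -0.55. Ifna1 turned to -0.67 without normalization. These percentiles describe 1 pair of arrays and are not tests. Without normalization 2 genes were at least 2-fold higher and 45 lower, with reference gene scaling 3 and 36, and with median scaling 19 and 4.

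At day 14, 35 genes of the angiogenesis arrays were above background in WT and not in HET, and 0 in HET and not in WT. Of 46 genes with a fold, 4 were at least 2-fold higher and 6 at least 2-fold lower in HET. The macrophage scavenger receptor gene Msr1 was 1.98 log2 units higher, with a density of 11617 against 5529. The receptor gene Tgfbr1 was 1.18 higher, Rpl13a 1.38, the angiogenesis inhibitor gene Serpinf1 1.01 and Gapdh 0.97. All but Rpl13a, at -0.0064 with reference gene scaling, kept their direction under the other scalings, and without normalization Msr1 was at 1.09, Tgfbr1 at 0.55, Gapdh at 0.39, Serpinf1 at 0.18 and Rpl13a at 0.07. In the list of TGF-beta signalling the 4 genes with a fold had a median of 0.84 at percentile 98.5, with Tgfbr2 at 0.90 and Tgfb1 at 0.78, while the 3 reference genes with a fold had a median of 0.97 at percentile 95.8. Without normalization Tgfbr2, Tgfb1 and Tgfb3 were below 0, at -1.50, -1.71 and -0.87. The linker protein gene Rsn (now Clip1) differed by -1.93, the protease gene Adamts8 by -1.80 or lower and the receptor gene Fgfr3 by -1.004, and these 3 kept their direction. Flt1, a VEGF receptor gene at the ceiling in WT, differed by -2.16, with densities of 42065 against 49470, Chga by -1.33 and the ribonuclease gene Rnase4 by -1.18. These 3 turned to 2.65, 0.32 and 0.49 under median scaling. Flt1 enters the count of lower genes at its measured value and was at -0.23 without normalization. Vegfb was at 0.59 after normalization and at -2.10 without it, and Vegfc at -0.30 or lower. Without normalization 1 gene was at least 2-fold higher and 47 lower, with reference gene scaling 1 and 49, and with median scaling 26 and 2.

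Over the 3 days, no gene passed the limma test of genotype on either array type. On the hypoxia arrays 0 of 73 genes passed, with a lowest adjusted p of 0.67 and 3 genes at an unadjusted p under 0.05, where chance alone gives 3.65. These were Rpl13a, above background on all 6 arrays but at its limit in WT at day 7, at 1.07 with a standard error of 0.24, and Igfbp1, which encodes an IGF-binding protein, and Plau. The latter pair were above background on 1 of 6 arrays each. Plau had a bound of -0.25 at day 10 after normalization and none without it, where its measured values differed by 0.88. On the angiogenesis arrays 0 of 96 genes passed, with a lowest adjusted p of 0.87 and 2 genes at an unadjusted p under 0.05, where chance gives 4.8. They were Col18a1, whose collagen gives rise to endostatin, which was above background on 1 of 6 arrays and has no fold, and the growth factor gene Hgf at 1.38 with a standard error of 0.54. Hgf was above background on 2 of 3 arrays of each genotype, at the ceiling on 2 in WT and 1 in HET. Igfbp1 and Col18a1 were outside the rule for named genes and are given because the counts are small. Hif1a had a mean difference of -0.86 with a 95% confidence interval from -3.01 to 1.29 on the hypoxia arrays and 0.05 with an interval from -1.11 to 1.22 on the angiogenesis arrays.

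No gene list moved in one direction with genotype by limma's fry. On the hypoxia arrays the adjusted p was 0.32 for other hypoxia response genes (6 members above background) and for reference genes (4), 0.35 for glycolysis and glucose transport (4), and 0.49 for chemokines and cytokines (3) and for transcription and cell signalling (4). For the angiogenesis arrays it was 0.54 for other hypoxia response genes (5), the VEGF family and receptors (6), angiopoietin and Tie (4), extracellular matrix and integrins (11), proteases and their inhibitors (9), angiogenesis inhibitors (10), endothelial markers (9) and reference genes (4). It was 0.94 for ephrins and Eph receptors (4), growth factors and receptors of the FGF, PDGF, EGF, HGF and IGF families (20), TGF-beta and BMP signalling (8) and chemokines and cytokines (11). In the mixed form, which asks for change in either direction, the list of extracellular matrix genes and integrins had an adjusted p of 0.0083, with Sparc at 0.80 and Thbs2 at -0.91, and with Col18a1, above background on 1 of 6 arrays, among its members. That call did not hold without background correction (0.22), with median scaling (0.61), with reference genes (0.70) or without normalization (0.78), nor without day 7, 10 or 14 (0.15, 0.77 and 0.58). Adjusted over the list alone, 0 members of any list passed. The tests of the angiogenesis inhibitors did not include Cxcl4 (now Pf4). The remaining lists had fewer than 3 members above background on an array type. On the hypoxia arrays these were the HIF pathway with 1 member, the VEGF family with 1, the growth factors with 1, TGF-beta signalling with 1, extracellular matrix with 2, proteases with 2, angiogenesis inhibitors with 1, apoptosis with 2 and osteoblast markers with 1. On the other array type they were the HIF pathway with 1, transcription and signalling with 2, osteoblast markers with 2 and osteoclast and macrophage markers with 1. The hypoxia arrays carry no member of the angiopoietin, ephrin, endothelial marker and osteoclast lists, and the angiogenesis arrays none of the glycolysis and apoptosis lists. The fixed lists of cartilage markers and of markers of skeletal muscle and red cells had no member on either array type, although the hypoxia arrays carry Mylpf, a skeletal muscle gene outside these lists.

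Between days 7 and 14, taken over both genotypes in the limma fit, 5 genes of the hypoxia arrays rose and 3 fell. Rpl13a rose by 3.17 log2 units (adjusted p = 0.032) from day 7 values at the background limit, with densities of 12.7 in WT and 437 on the array labelled HET against 12.7 and 391 for the brightest control spots. The ribosomal protein gene Rps7, above background on all 4 arrays, fell by 5.30 (standard error 0.32, adjusted p = 0.025), from densities of 32635 and 27063 to 496 and 846. The other 4 genes that rose were below background on both day 7 arrays. The cytokine gene Il1a was at least 6.32 higher at day 14, where its densities of 48703 in WT and 45094 in HET lay at and near the ceiling. Its limma adjusted p of 0.032 belongs to the fitted difference of 7.52, which uses day 7 values below background, and not to the bound. Rpl32 was at least 1.91 higher and Plod3, a collagen-modifying enzyme gene, at least 1.68 higher, with the same adjusted p for their fitted differences. The cytokine receptor gene Il6st had no fold. The other 2 genes that fell in the fit, Agtpbp1 among them, were above background on no array of either day and have no fold. Not every call held without normalization. Il1a and Il6st still passed (limma adjusted p = 0.018 and 0.043), while Agtpbp1 was at -0.20 (limma adjusted p = 0.87).

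On the angiogenesis arrays 13 genes were higher and 11 lower at day 14 than at day 7 in the same test. All 13 were below background on both day 7 arrays, so that differences from day 7 are bounds. The adjusted p-values given with them are those of the fitted differences and not of the bounds. The growth factor gene Fgf7, at the ceiling on both day 14 arrays, was at least 2.71 log2 units higher (adjusted p = 0.0039), with densities of 40.6 and 194 at day 7 and 49760 and 49473 at day 14. Thbs1, at the ceiling on both as well, was at least 2.06 higher (adjusted p = 0.014), the VEGF receptor gene Flt1, at the ceiling in WT, at least 1.58 (adjusted p = 0.0039), and Hgf, at the ceiling on 1 array, at least 0.94 (adjusted p = 0.016). Another 8 genes had no fold after normalization. Among these, the bounds without normalization were 6.45 for Tgfbr1, 6.15 for Tgfb3, 4.55 for Msr1, 4.47 for the matrix protease gene Mmp9, 3.74 for Efnb2 and 2.98 for Cd36. The number of lower genes depended on the scaling, with 8 under median scaling and 0 without normalization, with reference gene scaling or in the series matrix values. Of the 11, 4 were above background on both arrays of both days, namely Rpl13a at -4.20, Hif1a at -3.98, Gapdh at -3.21 and Ppia at -2.89, with Ppia at the ceiling on both day 7 arrays and Gapdh on 1. Without normalization these were at 1.25, -0.74, -0.70 and -0.44. Csf3, above background on 1 day 7 array and on no day 14 array, had a bound of -4.77 after normalization and none without it, where its measured values differed by -1.26. Edg1 (now S1pr1), Vegfb, Mmp2, Ephb4 and Vegfa were below background on both day 7 arrays and above it on 1 or 2 day 14 arrays, so the lower value at day 14 in the fit has no fold, and their unnormalized differences were 0.22, 2.13, 1.20, 1.08 and 1.80, all above 0.

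The 2 array types share 12 genes, which gives a second measurement of a genotype difference where a gene was above background on at least 1 array of the pair on both types. Genes with only a bound, and genes at the ceiling on both arrays of a pair, were taken at their measured value. Across these genes Pearson's r between the array types was 0.87 at day 7 (7 genes), 0.17 at day 10 (9 genes) and 0.26 at day 14 (9 genes), and Spearman's rho was 0.37, 0.18 and 0.27. Genes are not independent replicates, and these values describe the arrays. The day 7 value rests largely on Chga, at -1.66 and -1.46. The direction was the same for 3 of 7, 3 of 9 and 3 of 9 genes, and 3, 2 and 2 genes had no direction because a difference was 0 on an array type. Ctgf, Gapdh, Ppia and Actb were at the ceiling on both hypoxia arrays at day 10, as were Ctgf and Actb at day 14. Their differences there are not folds. The genes of opposite direction at day 10 were Ctgf, Ppia, Actb and Chga, of which only Chga was below the ceiling on the hypoxia arrays. At days 10 and 14, r was -0.64 and -0.21 without normalization.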

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

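All tests in this part were chosen after the result was seen. The HET minus WT difference of Hif1a had opposite signs at different days, with both array types above 0 at day 7 (0.71 on the hypoxia array and 0.35 on the angiogenesis array) and both below 0 at day 10 (-2.22 and -0.19). At day 14 it was -1.06 and 0.00. The difference between days was not tested, since each value comes from 1 pair of arrays. An exchange of the WT and HET labels at day 7 is a candidate explanation, and it would make the other genes run against their later differences. Across 16 genes measured on all 6 hypoxia arrays, Spearman's rho between the day 7 difference and the mean of the later ones was -0.29 (two-sided permutation p = 0.283), and across 6 genes of the angiogenesis arrays it was 0.49 (exact two-sided permutation p = 0.344). Both had an adjusted p of 0.344, so the exchange stays open. A gain in density over the whole array stays open on both array types. On the hypoxia array Hif1a lay 2.03 SD above the median of the 6 other measured genes dim enough in WT to rise as far, and 1.48 SD above that of the 7 that could rise by at least 1 log2 unit, and on the angiogenesis array it lay 0.17 SD above that of only 3. A difference between the genotypes that depends on the day, or a probe that reads an altered transcript, may also account for it, which was not tested.

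The second file of the angiogenesis sample labelled HET at day 7 was set aside because its values equal those of the WT day 7 array in 112 of 112 spots. It holds no further measurement of the HET sample.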

How the results depend on the processing

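No paired analysis was possible because each group has 1 array of each type, beyond the day block of the genotype fit, which sets the WT and HET arrays of a day against each other, and 0 genes passed without that block too. The alternative without normalization and without day 7 was chosen after seeing the data. The second file of the angiogenesis sample labelled HET at day 7 was not run as an alternative, alone or in the mean, since it copies the WT day 7 array. What limits these arrays is signal over background, with 9 to 91 of 100 genes above it, and the ceiling. The genotype tests gave 0 genes and 0 gene lists in one direction under each alternative, with 1 exception. When only the 9 genes above background on all angiogenesis arrays were tested, 2 passed, Chga at -1.04 (limma adjusted p = 0.012) and Sparc at 0.80 (0.042), in a fit that gave all 9 genes the same standard error of 0.27. In the mixed form of fry, the reference genes of the hypoxia arrays had an adjusted p of 0.19, and 0.036 without day 14 and 0.026 over genes above background on all arrays. For the main comparisons 131 alternative values stayed within the limits set for no change, 69 moved and 8 turned direction. For named genes 1125 stayed, 238 moved, 35 lost their threshold in the same direction and 37 turned direction. The values of the main comparisons that moved or turned and the named genes that turned follow, and beyond the shifts given next the cause was not tested.

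Scaling shifted the median HET minus WT difference over all genes. At days 7, 10 and 14 it was 0.01, 0.05 and -0.02 on the hypoxia arrays and -0.01, -0.06 and 0.16 on the angiogenesis arrays after quantile normalization. Without normalization it was 0.34, 1.66 and -0.44, and 1.17, -1.22 and -2.04. With reference genes it was -0.30, 1.06 and -0.08, and 0.89, -0.81 and -2.11. With each array scaled to its median it was -0.03, -0.49 and 0.64, and 0.07, 0.40 and 0.84.

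With each array scaled to its median, the genes at least 2-fold higher in HET on the hypoxia arrays numbered 7 at day 7 (3 after quantile normalization), 2 at day 10 (6) and 13 at day 14 (7), and those lower 1 (2), 21 (7) and 5 (8). The angiogenesis arrays gave 19 higher at day 10 (6) and 26 at day 14 (4), and 2 lower at day 7 (1), 4 at day 10 (10) and 2 at day 14 (6). Between days 7 and 14, 21 of their genes were higher (13). Chga turned to 0.048 at day 7, and Il1b, Il6 and Rps2 to -0.78, -0.52 and -1.61 at day 10, on the hypoxia arrays. On the angiogenesis arrays Thbs2 turned to 1.26 at day 10, and Chga, Flt1 and Rnase4 to 0.32, 2.65 and 0.49 at day 14. The correlation between the array types turned to -0.64 at day 10 (0.17) and -0.21 at day 14 (0.26), as it also did with reference gene scaling and without normalization, since each of these shifts all genes of an array by 1 constant.

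With each array scaled to its reference genes, the hypoxia arrays gave 6 genes higher at day 7 and 21 at day 10, and 1 lower at day 7 and 17 at day 14. The angiogenesis arrays gave 2, 3 and 1 higher at days 7, 10 and 14, and 36 and 49 lower at days 10 and 14. Rps2 turned to -0.064 on the hypoxia arrays at day 10, Thbs2 to 0.058 on the angiogenesis arrays at day 10 and Rpl13a to -0.0064 there at day 14. Between days 7 and 14, 29 angiogenesis genes were higher and 0 lower (11). The fitted differences turned to 0.19 for Edg1, 1.05 for Ephb4, 1.17 for Mmp2, 1.22 for Rpl13a, 1.77 for Vegfa and 2.10 for Vegfb.

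With no normalization between arrays, the hypoxia arrays gave 7, 24 and 2 genes higher at days 7, 10 and 14, and 1, 3 and 18 lower. The angiogenesis arrays gave 2, 2 and 1 higher, and 45 and 47 lower at days 10 and 14. Chga turned to 0.42 at day 7, Spnb2 to 0.082 at day 10 and Tgfb1 to -0.038 at day 14, all on the hypoxia arrays. Between days 7 and 14, 20 angiogenesis genes were higher and 0 lower. The fitted value of Edg1 turned to 0.22, of Ephb4 to 1.08, of Mmp2 to 1.20, of Rpl13a to 1.25, of Vegfa to 1.80 and of Vegfb to 2.13.

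With the series matrix values, the hypoxia arrays gave 7, 21 and 2 genes higher and 1, 2 and 22 lower at days 7, 10 and 14, and the angiogenesis arrays 10, 1 and 1 higher, and 27 and 30 lower at days 10 and 14. Chga turned to 0.30 at day 7, Spnb2 to 0.070 at day 10 and Tgfb1 to -0.044 at day 14 on the hypoxia arrays. The correlation between array types turned to -0.64 at day 10 and -0.40 at day 14. Between days 7 and 14, 0 hypoxia genes were higher (5) or lower (3) and 0 angiogenesis genes lower. Agtpbp1 turned to 0.24 on the hypoxia arrays. On the angiogenesis arrays Csf3 and Edg1 turned to 1.77 each, Ephb4 to 2.31, Mmp2 to 2.49, Rpl13a to 1.28, Vegfa to 2.28 and Vegfb to 2.31.

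With no background correction, 0 angiogenesis genes were higher at day 7 (1) and 4 hypoxia genes lower at day 10 (7). With an offset 5 times higher, the angiogenesis arrays gave 0 genes higher at day 7, 4 lower at day 10 and 2 higher at day 14, and the hypoxia arrays 4 lower at day 10 and 5 lower at day 14. With no filter on dim genes, which adds genes below background, the hypoxia arrays gave 17 higher and 17 lower at day 7 and 19 each at day 14, and the angiogenesis arrays 29 higher and 25 lower at day 7 and 12 lower at day 14. With only genes above background on all arrays compared, which leaves fewer genes, 1 gene was higher at day 14 than at day 7 on the hypoxia arrays, and 1 was higher and 5 lower on the angiogenesis arrays. With no genotype term, 5 hypoxia genes were lower at day 14 than at day 7.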

Other observations

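The genes and tests in this part were chosen after the values were seen, except the counts over other splits of the arrays. The test with 1 background threshold at the brightest control spot of any array was chosen after seeing the data too. Only its prediction was written before its result.

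Fabp4, a fatty acid binding protein gene of adipocytes and macrophages, stood at 1217 in WT and 1393 on the array labelled HET at day 7, at 44652 and 43925 at day 10, and at 816 and 388 at day 14. The lowest density of the day 7 array labelled HET was 248, against 0 in WT, so that pair does not give the direction of a difference. With background correction and without normalization Fabp4 differed by -0.09 at day 7. Mylpf, a myosin light chain gene of fast skeletal muscle, stood at 29943 and 15174 at day 7, 49185 and 49167 at day 10, and 13310 and 8512 at day 14. The proteasome gene Psmb3 was at 39666 and 37155 at day 7 and at 1813 and 2575 at day 14. The bone collagen gene Col1a1 was near or at the ceiling on the hypoxia arrays, between 41175 and 49757. These are densities of single arrays.

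The angiogenesis arrays of day 7 held 9 genes above background in WT and 12 on the array labelled HET, against 44 to 91 later. Whether the background threshold was set too high on the day 7 arrays stays open. The WT array held 9 genes above the lowest threshold of the 6 arrays (162), against at least 47 on each later array. Its median density was only 35.0, however, and 1 of its 6 control spots lay above 162, so that threshold may still be high for this array. On the array labelled HET, 49 genes lay above the lowest threshold, as did all 6 of its control spots. The counts above the brightest control spot of any array were at most 11 at day 7 and at least 33 later. They do not decide the question, because that threshold lies above both day 7 arrays' own and can only lower their counts. Weaker labelling or exposure stays open, since Gapdh, Ppia and Rpl13a, the reference genes not at the ceiling on every array, were brighter at day 7 than at a later day in 9 of 12 comparisons, 4 of 4 each for Gapdh and Ppia but 1 of 4 for Rpl13a. A difference between early and later callus, or one in the amplification of low-abundance RNA at day 7, may account for the pattern, and neither was tested.

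At day 14 the angiogenesis arrays held 79 genes above background in WT and 44 in HET. A loss by 1 factor for every gene of the HET array stays open. The 3 reference genes below the ceiling were at 0.39 (Gapdh), 0.07 (Rpl13a) and -0.17 (Ppia) without normalization. They lay over 2 SD of repeated spots above the median of -1.50 of the 33 other genes measured on both arrays. That SD is the spread of spots within an array, and the 33 genes ran from -3.90 to 1.09, a range that holds all 3 values. A loss that differs between genes stays open as well. Of these 36 genes, 1 was brighter on the HET array by more than 2 SD and 22 were dimmer by that much. Poorer RNA in a HET pool used for both array types stays open too, since the hypoxia HET array held 46 genes above background against 42 in WT, yet its unnormalized median difference was -0.74. Above the lowest threshold of the hypoxia arrays the counts were 63 in HET and 82 in WT. With 4 control spots of the HET array and 6 of the WT array above it too, they do not decide the order. A difference between the genotypes at day 14 cannot be told apart from these, with 1 array per group.

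For the genotype effect over the 3 days, 7 of the 10 splits of the 6 hypoxia arrays gave at least the 3 genes of the real split at an unadjusted p under 0.05, and the highest other split gave 15. On the angiogenesis arrays 7 of 10 splits gave at least the 2 genes of the real split, and the highest other gave 33, several times the real count. The structure behind this is the day pairs. In 6 of the 10 splits both arrays of a day lie on one side, so that with day as a block only 1 pair of arrays sets the effect, and the 15 and the 33 come from such splits. The 4 splits with 1 array of each day on each side gave, beside the real 3 and 2 genes, at most 5 on the hypoxia arrays and 3 on the angiogenesis arrays, and 3 of the 4 gave at least the real count on either type. With 10 splits no share under 0.05 is possible.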
